A study of Mus musculus with 22 samples.

How the data were processed

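RNA was measured in sorted gamma-delta thymocytes of female C57BL/6 mice, aged 8 weeks, on 22 arrays with 1 array per sample. Per the labels, total RNA was taken up in Trizol and labelled with biotin in 1 colour. The array was an Affymetrix mouse exon array summarised per transcript cluster. The deposited values are log2 expression values, which the submitters' processing notes credit to RMA in the oligo package (versions not given in the sources used here). RMA corrects for background, equalises the distributions of the arrays and summarises the probes of a probe set. The SD of the deposited log2 values still ran from 1.61 to 2.09 between arrays, so their distributions were not equal. Whether all arrays were normalised together could not be told. The median log2 value of an array lay between 4.43 and 4.76, and all values lay between 0.44 and 13.34, with no sign of further centring or scaling by gene. The genome build behind the probe annotation is not given in the sources used here, and no positions are reported.

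The table held 16755 probe sets. Of these, 14996 listed 1 gene symbol, 1019 listed several and 740 listed none. Only probe sets with 1 symbol were analysed by gene, which left out the gene that encodes CD24 and the gamma-chain segments. A gene with more than 1 probe set (135 of 14860 genes) was represented by the probe set of highest mean over the 22 arrays. Symbols were checked by gene identifier against a RefSeq table: 14941 could be matched and 0 differed. A gene was tested if its log2 value exceeded the median of the whole table (4.55) on at least 3 arrays, regardless of which, and 8545 genes passed.

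The arrays were grouped by gamma-chain subset and stage. Limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 22 arrays, so that groups of 3 or 4 arrays shared an estimate of the spread, and moderated it by empirical Bayes (prior degrees of freedom 4.47). The contrasts were Vg1.1+ minus Vg2+ at each stage, each later stage minus the one before it in each subset, and the difference of those steps between the subsets. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes of each contrast, a threshold of 0.05 and no minimum fold. Replicates carry numbers in the labels, which were not taken as pairs. Genes shared by both subsets were those past the threshold in both steps in 1 direction, set beside the product of the list sizes over the number of tested genes. The distance between subsets was the mean of 1 minus Pearson r over pairs of arrays of different subsets, minus that over pairs within a subset, with a one-sided exact permutation test.

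The 17 gene lists were the IL-17 list, the type 1 and cytotoxic list, the innate-like effector list, and those for T-cell receptor response, early T precursors, cell cycle, egress and homing, cytokine receptors and survival, interferon response, antigen processing with MHC class I, and glycolysis. Marker lists covered alpha-beta lineage thymocytes, myeloid and dendritic cells, thymic epithelium, B cells, erythroid cells and the sorted proteins with the gamma-chain segments. Lists with at least 5 tested genes were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The estimated correlation comes from groups of few arrays and varies between lists.

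Genes to be named were the 10 with the largest positive and the 10 with the largest negative log2 difference past the threshold in each contrast, and up to 4 members of each list per contrast, at most 2 in each direction. Also named were a fixed set of regulators in every contrast, of which Sox13, Tbx21, Id3, Egr2 and Cd44 were tested, and the 10 shared genes per direction with the largest mean difference. The text gives a selection of these, and predicted genes were left out. A short list of mast cell transcripts was written after the values of Cpa3 and Kit had been seen and before its own were. The myeloid markers C1qb, H2-Aa and Cd68 and the array-by-array values in the closing section were also chosen after values had been seen.

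The samples, contrasts, tests, filter, gene lists, naming rule and first set of alternatives were fixed before the data were examined. These alternatives were the replicate number as a block, no filter, a stricter filter (above the 65th percentile, 5.46, on at least 3 arrays), empirical Bayes with trend and robust options, a fit to the groups of the contrast alone, array weights, arrays numbered 1 to 3 alone, cyclic loess on top of the deposited values, a minimum fold of 2, all 9450 probe sets past the filter for the counts, the 1000 most variable genes for the distances, and each array left out in turn. The fit without the pair of arrays of narrowest spread and the fit with the spread of each array as a covariate were added after the data had been seen.

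The fits were tested on simulated data with the spread of the real genes and arrays, each gene drawn independently. In each contrast a fixed number of genes was changed, 2-fold and 4-fold in equal parts, and the others were left unchanged. Of genes given a 2-fold change, 87% to 93% were called in a comparison of a pair of groups and 67% to 75% in a difference of steps. Of genes given a 4-fold change, 95% to 100% were called. Of the calls, 0% to 13.8% were genes without a change, the highest share being at CD24-CD73+. These shares hold for that mix of changes and for independent genes, and may overstate the power in the real data. There, differences above 2-fold at CD24+CD73+, such as that of the gene Psmb9, did not pass. No columns of values per sample were left out.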

Results

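Gene expression was measured in gamma-delta thymocytes of female C57BL/6 mice aged 8 weeks, sorted by the variable segment of the gamma chain (Vg1.1+ or Vg2+) and by the surface proteins CD24 and CD73. CD24 is carried by immature thymocytes, and CD73 marks thymocytes that have committed to the gamma-delta lineage. The sorts gave 3 stages in each subset, here taken in the order CD24+CD73-, CD24+CD73+ and CD24-CD73+. The 22 arrays fell into 6 groups. Vg1.1+ cells had 4, 3 and 4 arrays at the successive stages, and Vg2+ cells had 3, 4 and 4. The series asks which genes the subsets share at each stage and when they diverge. The number of arrays limits the precision of every value. The labels call the replicates biological without saying whether each came from separate animals, so p-values measure the spread between these samples alone.

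The sorted protein CD73 was matched by its transcript. Nt5e, which encodes CD73, had a mean log2 value of 3.75 ± 0.18 (SD, n = 4) in Vg1.1+ CD24+CD73- cells, 8.05 ± 0.23 (n = 3) in CD24+CD73+ cells and 8.33 ± 0.59 (n = 4) in CD24-CD73+ cells. In Vg2+ cells the means were 3.42 ± 0.41 (n = 3), 7.22 ± 0.35 (n = 4) and 7.33 ± 0.24 (n = 4). The first principal component of the tested genes held 35.6% of the variance and ordered the arrays by stage. The second held 19%, and its lowest scores were those of the 2 arrays with the narrowest spread of log2 values. These were Vg1.1+ CD24-CD73+ replicate 1 (SD 1.61) and Vg2+ CD24+CD73+ replicate 3 (SD 1.71), against 1.81 to 2.09 on the other arrays.

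**Figure D1:**
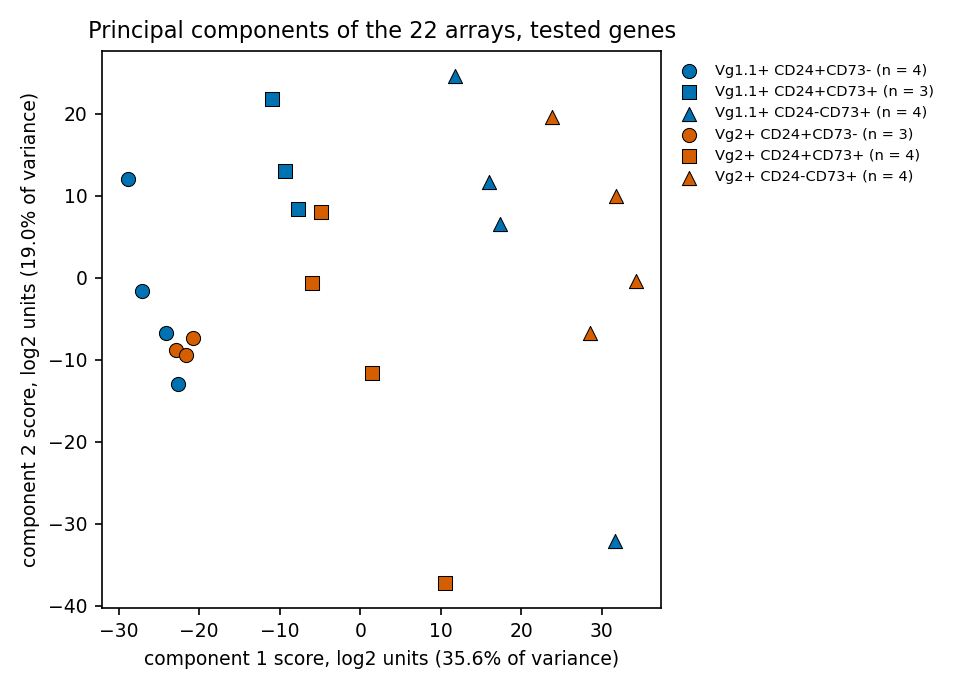
Scores of the 22 arrays on the first 2 principal components of the tested genes (log2 units), with colour for the gamma-chain subset and shape for the stage. The first component (35.6% of the variance) follows the stage, and the 2 arrays of narrowest spread have the lowest scores on the second (19%).

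The step from CD24+CD73- to CD24+CD73+ in Vg1.1+ cells asks what changed as CD73 appeared. The transcripts that rose included those of a chemokine and of natural killer receptors. The chemokine Ccl5 rose by 5.01 ± 0.28 (log2 difference ± SE, n = 3 against 4 arrays), from a group mean of 4.57 to 9.58. The lectin-like receptors Klrb1a, Klrd1 and Klre1 rose by 3.64 ± 0.27, 3.07 ± 0.22 and 2.96 ± 0.31. Dntt, the terminal transferase that adds bases to rearranging receptor genes, fell (-3.76 ± 0.45), as did the granzyme Gzma (-3.15 ± 0.24) and the Src-family kinase Blk (-3.13 ± 0.32). Receptors Crtam and Slamf7, the adaptor Fcer1g and the surface protein Cd7 rose by 3.24 ± 0.26, 2.95 ± 0.26, 3.31 ± 0.37 and 3.06 ± 0.50. The C-type lectin Clec12a (-2.62 ± 0.20), the water channel Aqp11 (-2.52 ± 0.45), the ETS factor Etv5 (-2.42 ± 0.22) and the peptide transporter Slc15a1 (-2.23 ± 0.18) fell too. Of the 17 measured genes of the type 1 and cytotoxic list, 8 rose and 2 fell (adjusted over the list alone, 9 higher and 3 lower), and the list passed camera, limma's gene set test (adjusted p = 1.6e-07, and adjusted p = 0.0192 with an estimated correlation). Gzma was among those that fell. Of the 15 genes of the IL-17 list none rose and 7 fell (adjusted over the list alone, 0 higher and 9 lower), among them Blk, Etv5, Sox13 (-1.56) and the interleukin 1 receptor Il1r1 (-2.18). Its adjusted p was 3.0e-09, and 0.0156 with an estimated correlation. Markers of alpha-beta lineage thymocytes fell in 4 of 7 cases (adjusted over the list alone, 1 higher and 5 lower), with Cd8b1 at -2.29 and an adjusted p of 0.0156 with an estimated correlation. Of the 7 markers 6 were highest on 1 array of the starting group, Vg1.1+ CD24+CD73- replicate 1, where Cd8b1 reached 7.74 against a mean of 6.13 on the other 3 arrays. Of the innate-like effector list 7 of 15 genes rose and 2 fell, and of the list of T-cell receptor response genes 4 of 17 rose and none fell (adjusted over the list alone, 10 higher and 3 lower, and 5 higher and 0 lower). Cd40lg rose by 2.16 ± 0.22, the transcriptional regulator Id2 by 1.84 ± 0.25 and the nuclear receptor Nr4a2 by 2.08 ± 0.31. Both lists passed with the preset correlation and not with an estimated correlation (adjusted p = 0.0742 and adjusted p = 0.327).

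Over this step in Vg1.1+ cells limma called 668 of 8545 genes, 373 higher and 295 lower. The balance turned with array weights (1227 higher and 1345 lower). Sox13, Tbx21, Id3, Egr2 and Cd44 differed by -1.56, 0.31, 0.60, 0.80 and 0.48 (adjusted p of 1.3e-06, 0.309, 0.517, 0.421 and 0.00338). Leaving out Vg1.1+ CD24+CD73+ replicate 1 lowered the count to 437, and leaving out Vg1.1+ CD24+CD73+ replicate 2 ended the call of Gata3, which fell by 0.89 ± 0.22 with all arrays (adjusted p = 0.0523 without that array).

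In Vg2+ cells the same step raised many of the same transcripts. Ccl5 rose by 5.47 ± 0.28 (n = 4 against 3 arrays), the chemokine Xcl1 by 4.09 ± 0.21, Klrd1 by 3.95 ± 0.22 and Klrb1a by 3.73 ± 0.27. The calcium-binding membrane protein Mctp1 rose by 3.31 ± 0.21, Slamf7 by 3.18 ± 0.26 and Cd40lg, the ligand of CD40, by 3.10 ± 0.22. Etv5 (-3.65 ± 0.22), Blk (-3.62 ± 0.32), Gzma (-3.17 ± 0.24) and Dntt (-3.04 ± 0.45) fell most. The DNA ligase Lig4 (-2.26 ± 0.34) and the endonuclease Endou (-2.83 ± 0.28) also fell. Of the type 1 and cytotoxic list 9 of 17 genes rose and 2 fell, and of the IL-17 list none of 15 rose and 8 fell (adjusted over the list alone, 11 higher and 2 lower, and 0 higher and 9 lower). Both passed camera with the preset correlation and with an estimated one (adjusted p = 0.0242 and 0.0246 with the latter). Among T-cell receptor response genes 6 of 17 rose and none fell (adjusted over the list alone, 9 higher and 0 lower; adjusted p = 0.231 with an estimated correlation), with Nr4a2 at 2.43 ± 0.31. Of the innate-like effector list 8 of 15 rose and 4 fell (adjusted over the list alone, 9 higher and 4 lower; adjusted p = 0.227 with an estimated correlation). The myeloid and dendritic cell marker list had 5 of 8 genes higher and none lower (adjusted over the list alone, 5 higher and 0 lower; adjusted p = 0.0603 with an estimated correlation). The largest rises were of Tyrobp (2.58 ± 0.24) and Fcer1g (2.29 ± 0.37), adaptors that natural killer receptors also use, and the others were of C1qb, H2-Aa and Cd68.

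Over this step in Vg2+ cells limma called 1045 genes, 497 higher and 548 lower (786 and 651 with the array spread as a covariate). Of the transcription factors and receptors followed throughout, Sox13, Tbx21, Id3, Egr2 and Cd44 differed by -1.70, 0.37, -0.07, 1.55 and 0.37 (adjusted p of 2.7e-07, 0.145, 0.938, 0.034 and 0.0176). The call of Egr2 ended when any 1 of 5 arrays was left out (adjusted p from 0.0646 to 0.161). These were Vg2+ CD24+CD73- replicates 1, 2 and 3 and Vg2+ CD24+CD73+ replicates 2 and 4. The call of Cd44 ended without Vg2+ CD24+CD73- replicate 3 (adjusted p = 0.14).

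The subsets shared part of this step. In both, 277 genes rose and 173 fell, where independent lists of those sizes would share 21.7 and 18.9. The log2 differences of the subsets correlated across all tested genes at r = 0.662, and genes are not independent replicates. A single gene was called in opposite directions among those falling in Vg1.1+ cells. The shared genes of largest mean difference were Ccl5, Nt5e and Klrb1a among those rising and Dntt, Blk and Gzma among those falling. The test of the difference itself, Vg1.1+ step minus Vg2+ step, called 8 genes. Xcl1 (difference of -2.02 ± 0.30), Spa17 (-1.82 ± 0.28), Tnfsf8 (-1.75 ± 0.17), Aspn (-1.19 ± 0.20) and Tgtp1 (-1.17 ± 0.18) rose less or fell more in Vg1.1+ cells. The chemokine receptor Ccr2 (1.28 ± 0.20) and the nucleotide-sugar transporters Slc35b4 (1.14 ± 0.18) and Slc35d1 (0.99 ± 0.17) went the other way. In camera 5 lists passed for this difference with the preset correlation, and the lowest adjusted p was 0.134 with an estimated correlation, for the alpha-beta lineage and the myeloid marker lists. The count of genes rose to 15 without Vg2+ CD24+CD73- replicate 1 and to 17 without Vg2+ CD24+CD73+ replicate 2. The call of Slc35d1 ended without Vg1.1+ CD24+CD73+ replicate 1, Vg1.1+ CD24+CD73+ replicate 2 or Vg2+ CD24+CD73- replicate 2 (adjusted p from 0.0579 to 0.0785).

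The step from CD24+CD73+ to CD24-CD73+ in Vg1.1+ cells asks what changed as CD24 was lost. The lipid-binding protein Fabp7 rose by 4.86 ± 0.25 (log2 difference ± SE, n = 4 against 3 arrays), from a mean of 2.51 ± 0.30 to 7.37 ± 0.55 (SD). The costimulatory receptor Icos rose by 3.87 ± 0.21, the cytokine Il4 by 3.81 ± 0.23, the chemokine receptor Cxcr3 by 3.70 ± 0.25 and the vitamin D receptor Vdr by 3.12 ± 0.29. The channel Trpm6, the interleukin 18 receptor Il18r1, Cd40lg and Ccr2 rose by 3.14 ± 0.11, 3.05 ± 0.15, 2.68 ± 0.22 and 2.67 ± 0.14. Cpa3, a carboxypeptidase best known from mast cells, fell (-3.32 ± 0.21), as did the receptor Cd200r1 (-2.07 ± 0.27), the histone deacetylase Hdac9 (-2.05 ± 0.21), the growth factor receptor Kit (-1.96 ± 0.18) and the nuclear receptor Nr4a1 (-1.93 ± 0.39). Of the innate-like effector list 9 of 15 genes rose and 1 fell, which was Nr4a1 (adjusted over the list alone, 9 higher and 2 lower; adjusted p = 0.0218 with an estimated correlation). Of the cell cycle list none of 28 rose and 22 fell (adjusted over the list alone, 0 higher and 25 lower; adjusted p = 0.0286 with an estimated correlation), with the kinesin Kif11 at -1.48 ± 0.27 and the topoisomerase Top2a at -1.35 ± 0.20. Of the IL-17 list 7 of 15 rose and 2 fell (adjusted over the list alone, 10 higher and 2 lower; adjusted p = 0.121 with an estimated correlation). The interleukin 23 receptor Il23r rose by 1.99 ± 0.28 and Blk by 1.64 ± 0.32, while the transcription factors Etv5 (-1.75 ± 0.22) and Sox4 (-1.55 ± 0.14) fell. Interferon response genes rose in 7 of 16 cases and fell in none (adjusted over the list alone, 8 higher and 0 lower; adjusted p = 0.141 with an estimated correlation).

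Over this step in Vg1.1+ cells limma called 957 genes, 366 higher and 591 lower. For this step, Sox13, Tbx21, Id3, Egr2 and Cd44 differed by 0.54, 0.51, -1.33, -0.59 and 0.88 (adjusted p of 0.0416, 0.0424, 0.0393, 0.452 and 3.6e-06). Leaving out Vg1.1+ CD24+CD73+ replicate 1 or Vg1.1+ CD24+CD73+ replicate 3 lowered the count to 623. The calls of Sox13, Tbx21 and Id3 ended without Vg1.1+ CD24+CD73+ replicate 1, Vg1.1+ CD24+CD73+ replicate 2 or Vg1.1+ CD24-CD73+ replicate 1. Those of Sox13 and Id3 also ended without Vg1.1+ CD24+CD73+ replicate 3, and those of Sox13 and Tbx21 without Vg1.1+ CD24-CD73+ replicates 3 or 4. The adjusted p then ran from 0.0571 to 0.135 for Sox13, from 0.0543 to 0.223 for Tbx21 and from 0.0651 to 0.161 for Id3.

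In Vg2+ cells the same step raised Ccr2 and Il18r1 again, beside other transcripts. The interleukin 23 receptor Il23r rose by 6.67 ± 0.26 (n = 4 against 4 arrays), from a mean of 2.59 ± 0.47 to 9.27 ± 0.28 (SD). The chemokine receptors Ccr6 and Ccr2 rose by 5.08 ± 0.27 and 5.08 ± 0.13, the membrane proteins Tmem176a and Tmem176b by 4.72 ± 0.18 and 3.97 ± 0.18, and Il1r1 by 4.64 ± 0.23. The matrix-binding protein Abi3bp, Il18r1, the leukotriene receptor Cysltr1 and Pxdc1 rose by 4.54 ± 0.12, 4.08 ± 0.14, 3.94 ± 0.16 and 3.94 ± 0.22. Cpa3 (-3.61 ± 0.20) and Cd200r1 (-2.47 ± 0.25) fell, as did the mitotic genes Nusap1, Kif11, Nuf2 and Bub1 (-2.20 ± 0.19, -2.14 ± 0.25, -2.08 ± 0.17 and -2.06 ± 0.22). Of the IL-17 list 13 of 15 genes rose, and the other 2, Etv5 (-1.74 ± 0.20) and Sox4 (-1.68 ± 0.13), fell (adjusted over the list alone, 13 higher and 2 lower; adjusted p = 0.00361 with an estimated correlation). Of the cell cycle list none of 28 rose and 24 fell (adjusted over the list alone, 0 higher and 27 lower; adjusted p = 0.00996 with an estimated correlation). Egress and homing genes rose in 7 of 15 cases and cytokine receptor and survival genes in 8 of 17, with 1 lower in each (adjusted over the list alone, 7 higher and 1 lower, and 8 higher and 3 lower). Both calls were lost with an estimated correlation (adjusted p = 0.247 and adjusted p = 0.379). The interleukin 7 receptor Il7r, in the latter list, rose by 1.86 ± 0.16, and the interleukin 2 receptor Il2ra by 2.53 ± 0.18. T-cell receptor response genes fell in 7 of 17 cases and rose in 1 (adjusted over the list alone, 1 higher and 8 lower; adjusted p = 0.379 with an estimated correlation), with Nr4a1 at -1.37 ± 0.36. The call of Nr4a1 ended with only these groups in the fit (adjusted p = 0.0791) and with arrays 1 to 3 alone (0.118). Innate-like effector genes rose in 6 of 15 cases and fell in 4 (adjusted over the list alone, 6 higher and 4 lower; adjusted p = 0.379 with an estimated correlation), with Icos at 3.06 ± 0.19.

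Over this step in Vg2+ cells limma called 1725 genes, 878 higher and 847 lower. Over the same step Sox13, Tbx21, Id3, Egr2 and Cd44 differed by 0.85, 0.31, -1.11, -0.66 and 1.75 (adjusted p of 3.2e-04, 0.155, 0.0439, 0.331 and 1.4e-11). The call of Id3 ended when any 1 of 6 arrays was left out (adjusted p from 0.0749 to 0.13), namely replicates 1, 2 and 4 of Vg2+ CD24+CD73+ and of Vg2+ CD24-CD73+.

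Part of this step was shared as well. In both, 171 genes rose (37.6 from independent lists) and 368 fell (58.6), and the differences correlated across genes at r = 0.466. Of the genes that rose in Vg1.1+ cells 12 fell in Vg2+ cells, and of those that fell 7 rose. Ccr2, Il18r1, Icos and Cxcr3 were among the shared genes that rose most, and Cpa3, Cd200r1, Mctp1 and Kit among those that fell most. The test of the difference, Vg1.1+ step minus Vg2+ step, called 432 genes, 156 of them with a higher value in Vg1.1+ cells and 276 with a lower one. Fabp7 (4.82 ± 0.34), Il4 (4.12 ± 0.32), Cd40lg (3.66 ± 0.30), Vdr (2.83 ± 0.39), the interleukin 25 receptor Il17rb (2.70 ± 0.27) and the cytokines Il21 (2.50 ± 0.23) and Il13 (2.19 ± 0.37) had the higher step in Vg1.1+ cells. Il23r (-4.68 ± 0.39), Ccr6 (-4.18 ± 0.40), Abi3bp (-3.98 ± 0.18), Il1r1 (-3.60 ± 0.34), Tmem176a (-3.53 ± 0.27) and the factor Hlf (-2.92 ± 0.23) had the lower step. Of the IL-17 list 10 of 15 genes had a lower step in Vg1.1+ cells and none a higher one (adjusted over the list alone, 0 higher and 10 lower; adjusted p = 0.00208 with an estimated correlation). Over the whole course from CD24+CD73- to CD24-CD73+ the difference was called for 340 genes, 128 higher and 212 lower. Fabp7 (4.97 ± 0.34), Il4 (3.98 ± 0.32), Vdr (3.37 ± 0.39), Il23r (-4.80 ± 0.39), Ccr6 (-4.53 ± 0.40) and Il2ra (-2.91 ± 0.26) were among them. Leaving out Vg1.1+ CD24+CD73+ replicate 1 or 3 lowered the count of 432 to 265 or 276.

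**Figure D2:**
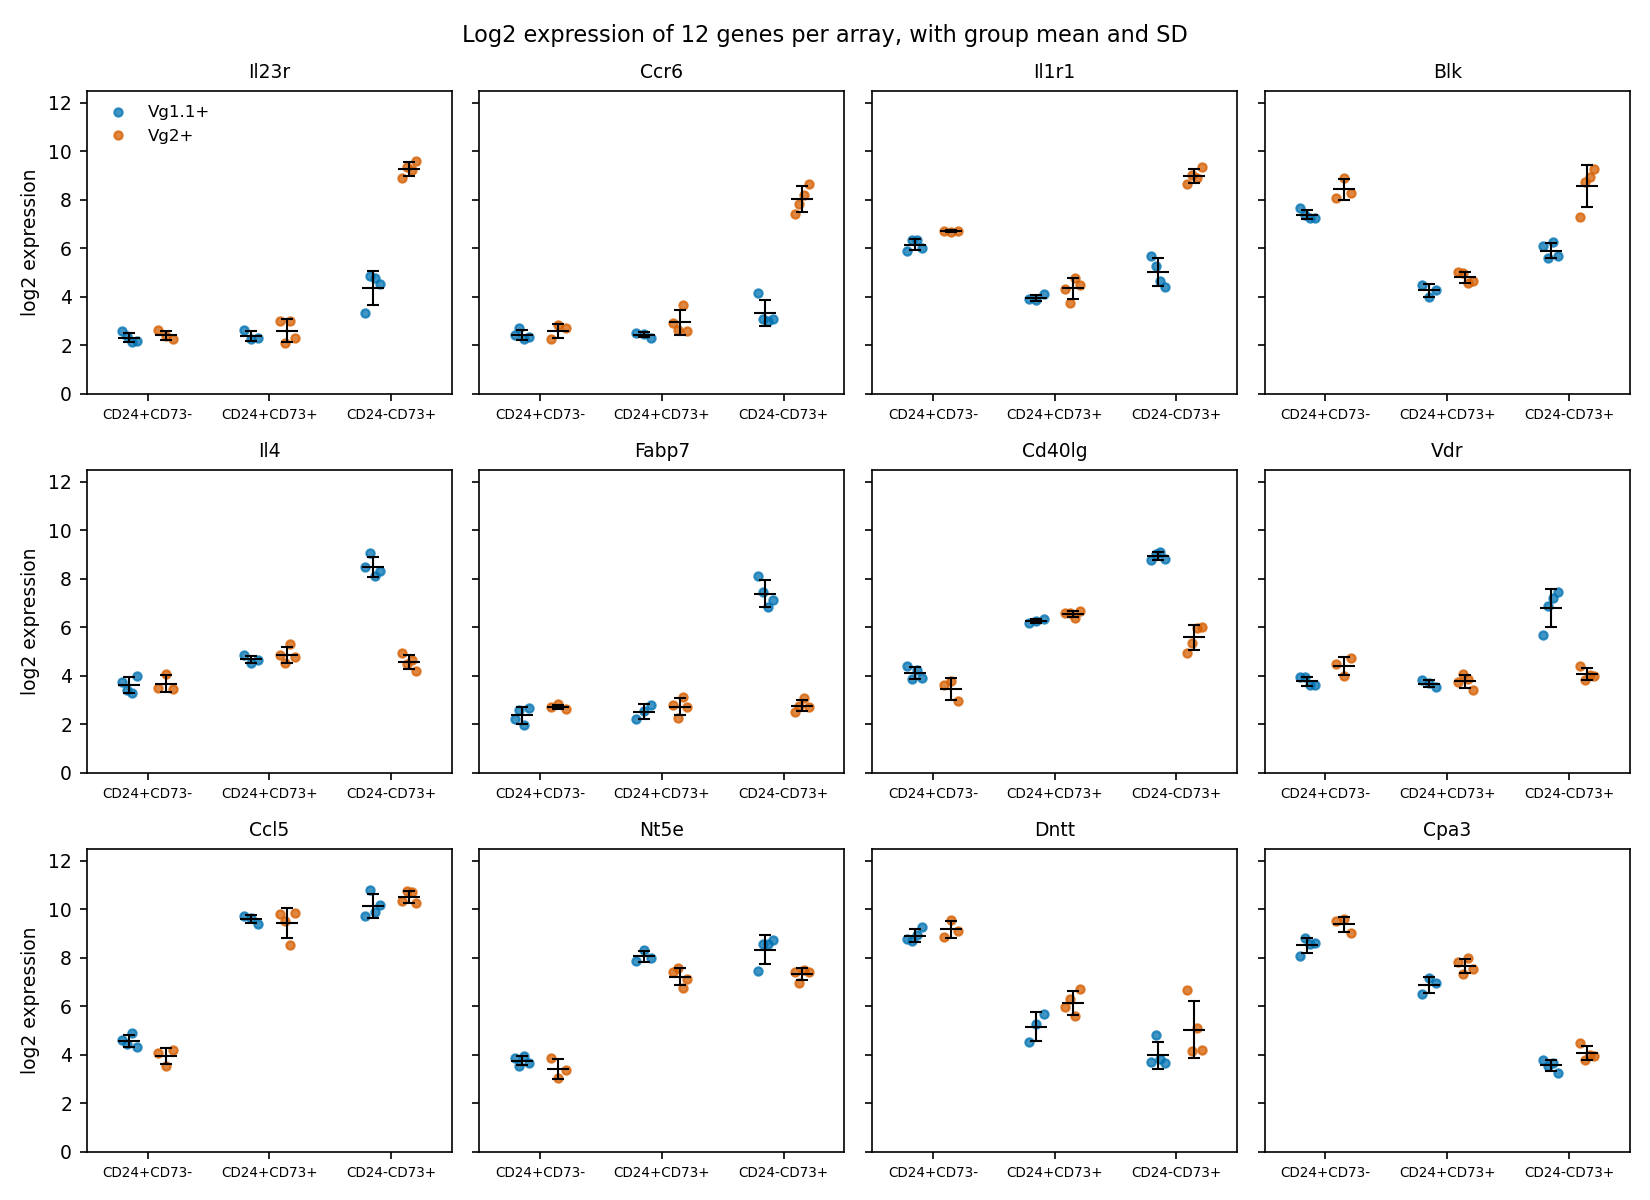
Log2 expression of 12 genes per array (points) at the 3 stages, in Vg1.1+ (blue) and Vg2+ (orange) cells, with bars for the group mean and SD. Il23r reached 9.27 in Vg2+ CD24-CD73+ cells and 4.37 in Vg1.1+ cells of that stage, while Il4 reached 8.48 in Vg1.1+ and 4.56 in Vg2+ cells.

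**Figure D3:**
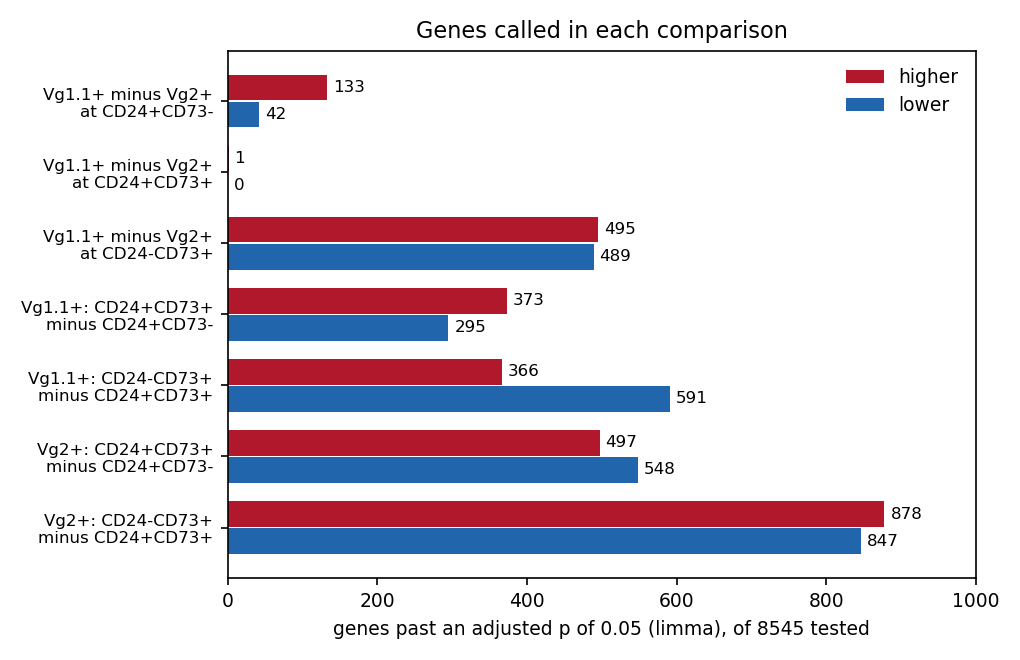
Number of genes past an adjusted p of 0.05 in each comparison, higher (red) and lower (blue), of 8545 tested genes. Between the subsets 175 genes were called at CD24+CD73-, 1 at CD24+CD73+ and 984 at CD24-CD73+. The low count at CD24+CD73+ does not show that fewer genes differed there.

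At the CD24+CD73- stage the subsets were compared directly. Vg1.1+ cells had more of Tnfsf8, the CD30 ligand, by 2.12 ± 0.12 (Vg1.1+ minus Vg2+, log2 difference ± SE, n = 4 against 3 arrays). Group means were 5.98 ± 0.12 and 3.86 ± 0.17 (SD). The chemokine Xcl1 was higher by 1.93 ± 0.21, Spa17 by 1.77 ± 0.20, the costimulatory receptor Cd28 by 1.49 ± 0.27, the surface glycoprotein Cd200 by 1.45 ± 0.25 and the actin-severing protein Scin by 1.34 ± 0.23. The nucleotide-sugar transporters Slc35b4 and Slc35d1 were lower in Vg1.1+ cells, at -0.93 ± 0.12 and -0.92 ± 0.12, as were the phosphatase Ppm1e (-0.89 ± 0.16), Tdrkh (-0.86 ± 0.14) and the nuclear receptor Rora (-0.79 ± 0.15). Of the cell cycle list 6 of 28 genes were higher in Vg1.1+ cells and none lower (adjusted over the list alone, 25 higher and 0 lower), with a mean difference of 0.61 and an adjusted p of 0.038 with an estimated correlation. The mean was 0.54 with the array spread as a covariate. T-cell receptor response genes were higher in 5 of 17 cases and lower in none, and IL-17 list genes lower in 2 of 15 and higher in none (adjusted over the list alone, 9 higher and 0 lower, and 0 higher and 4 lower). Both lists passed with the preset correlation (adjusted p = 3.3e-06 and 9.2e-06) and not with an estimated correlation (adjusted p = 0.261 and adjusted p = 0.106). Between the subsets Sox13, Tbx21, Id3, Egr2 and Cd44 differed by -0.48, -0.06, 0.23, 1.77 and -0.20 (adjusted p of 0.173, 0.943, 0.911, 0.0582 and 0.427).

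Limma called 175 genes at this stage, 133 higher and 42 lower in Vg1.1+ cells. Arrays of different subsets lay farther apart than arrays of one subset, by 0.0107 in mean 1 minus Pearson r (one-sided exact permutation p = 0.0286, the smallest that the 35 splits allow). The count of 175 fell to 81, 79 or 63 without Vg2+ CD24+CD73- replicate 1, 2 or 3, and to 95, 81 or 102 without Vg1.1+ CD24+CD73- replicate 2, 3 or 4. Of the called genes 21 were considered for naming, and the calls of 10 ended with 1 array left out. They included Icos (-1.01, adjusted p = 0.0717 without Vg2+ CD24+CD73- replicate 1) and Il7r (0.95, 0.0517 without Vg2+ CD24+CD73- replicate 3), while Nr4a1 (1.51) and Mcm7 (0.89) lost theirs without any 1 of the 7 arrays (0.0901 to 0.154 and 0.0787 to 0.205).

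At the CD24+CD73+ stage few single genes passed the threshold between the subsets. Kbtbd4, a Kelch-repeat protein, was higher in Vg1.1+ cells by 0.79 ± 0.13 (n = 3 against 4 arrays), with means of 5.77 ± 0.05 and 4.98 ± 0.26 (SD). It was the 1 gene limma called, with none lower, while 1579 genes had an unadjusted p under 0.05, more than the 1089 at CD24+CD73-. The share of genes that differ, estimated by limma from the p-values, was 33.9% here, 12.1% at CD24+CD73- and 24.1% at CD24-CD73+, so it did not follow the counts. The median difference over all tested genes was 0.074 here, 0.018 at CD24+CD73- and 0.008 at CD24-CD73+, and 0.003 here after cyclic loess. Whether that shift adds to the 33.9% and to the 1579 genes was not tested. The low count does not show that fewer genes differed, and the estimate does not show that more did. Nr4a1 differed by 1.16 (adjusted p = 0.192), the thymidine kinase Tk1 by 1.21 (0.192), the T-cell receptor subunit Cd3e by 1.26 (0.221) and the proteasome subunit Psmb9 by 1.36 (0.201). At this stage Sox13, Tbx21, Id3, Egr2 and Cd44 differed by -0.34, -0.12, 0.90, 1.01 and -0.09 (adjusted p of 0.271, 0.666, 0.26, 0.268 and 0.601). In the cell cycle list no gene passed over all genes (adjusted over the list alone, 6 higher and 0 lower). Its mean difference was 0.30, and 0.11 with the array spread as a covariate. With the preset correlation 6 lists passed. The lists of cell cycle, T-cell receptor response, glycolysis, and antigen processing genes were higher in Vg1.1+ cells, and those of alpha-beta lineage markers and of myeloid and dendritic markers lower. None passed with an estimated correlation, where the myeloid list had the lowest value (adjusted p = 0.237).

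The subsets lay apart by 0.00774 at this stage (one-sided exact permutation p = 0.2). The value fell to -0.00439 without Vg1.1+ CD24+CD73+ replicate 1 and to -0.00112 without Vg1.1+ CD24+CD73+ replicate 3. It was 0.00454 without Vg1.1+ CD24+CD73+ replicate 2, 0.0172 without Vg2+ CD24+CD73+ replicate 4 and 0.0278 without Vg2+ CD24+CD73+ replicate 2. Without Vg2+ CD24+CD73+ replicate 2 limma called 97 genes, and without Vg2+ CD24+CD73+ replicate 4 it called 7. The call of Kbtbd4 ended without any of the 3 Vg1.1+ arrays, or without Vg2+ CD24+CD73+ replicate 1 or 3 (adjusted p from 0.123 to 0.373), and the count was then 0.

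At the CD24-CD73+ stage limma called the most genes between the subsets. Vg1.1+ cells had more Fabp7 by 4.61 ± 0.23 (Vg1.1+ minus Vg2+, log2 difference ± SE, n = 4 against 4 arrays), more Il4 by 3.92 ± 0.22, more Cd40lg by 3.36 ± 0.20 and more Il17rb by 3.13 ± 0.19. Mean Il4 was 8.48 ± 0.41 in Vg1.1+ and 4.56 ± 0.30 in Vg2+ cells (SD). Vg2+ cells had more Il23r (difference of -4.90 ± 0.26), Ccr6 (-4.70 ± 0.27), Abi3bp (-4.37 ± 0.12), Il1r1 (-3.98 ± 0.23) and Tmem176a (-3.86 ± 0.18). Vdr (2.74 ± 0.27), the non-coding transcript H19 (2.72 ± 0.34), Flrt2 (2.36 ± 0.18), Trpm6 (2.25 ± 0.11) and the folate receptor family member Izumo1r (2.24 ± 0.20) were higher in Vg1.1+ cells, as was the factor Myb (1.53 ± 0.20). Pxdc1 (-3.56 ± 0.22), Cysltr1 (-3.40 ± 0.16), Hlf (-3.10 ± 0.16), Plekhf1 (-2.95 ± 0.30) and Il2ra (-2.30 ± 0.18) were lower. Of the IL-17 list 13 of 15 genes were lower in Vg1.1+ cells and 1, Etv5, higher (adjusted over the list alone, 2 higher and 13 lower; adjusted p = 4.4e-04 with an estimated correlation). The cell cycle list had 17 of 28 genes higher in Vg1.1+ cells and none lower (adjusted over the list alone, 23 higher and 0 lower; adjusted p = 0.0713 with an estimated correlation), with a mean difference of 0.60, and 0.62 with the array spread as a covariate. Cytokine receptor and survival genes were lower in 7 of 17 cases and higher in none, with the interferon gamma receptor Ifngr1 at -2.23 ± 0.11 (adjusted over the list alone, 0 higher and 7 lower; adjusted p = 0.0713 with an estimated correlation). Egress and homing genes were lower in 7 of 15 and higher in 1, with the receptors Gpr183 at -1.84 ± 0.16 and Cxcr6 at -1.42 ± 0.31 (adjusted over the list alone, 1 higher and 10 lower; adjusted p = 0.201 with an estimated correlation). The call of Cxcr6 ended with only these groups in the fit (adjusted p = 0.0628). T-cell receptor response genes were higher in 5 of 17 cases and innate-like effector genes in 6 of 15, with none and 4 lower (adjusted over the list alone, 8 higher and 1 lower, and 7 higher and 4 lower; adjusted p = 0.371 with an estimated correlation for each).

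Limma called 984 genes at this stage, 495 higher and 489 lower in Vg1.1+ cells (839 and 542 without the pair of arrays of narrowest spread). The distance between the subsets was 0.0325 (one-sided exact permutation p = 0.0286, the smallest that the 35 splits allow) and 0.0253 without Vg2+ CD24-CD73+ replicate 4 (one-sided exact permutation p = 0.0571). Here Sox13, Tbx21, Id3, Egr2 and Cd44 differed by -0.66, 0.08, 0.68, 1.09 and -0.97 (adjusted p of 0.00589, 0.846, 0.327, 0.127 and 1.9e-07). The call of Etv5, higher by 0.66 ± 0.20, ended when any 1 of 6 of the 8 arrays was left out (adjusted p from 0.0812 to 0.112), all but Vg1.1+ CD24-CD73+ replicate 1 and Vg2+ CD24-CD73+ replicate 3.

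The genes that separated the subsets at the first stage were looked up later. Of the 175 genes called at CD24+CD73-, 77.1% had the same sign at CD24+CD73+ and 79.4% at CD24-CD73+. At CD24+CD73+ some of this agreement needs no lasting difference of single genes. There the median difference of all tested genes was 0.074, and 76% of the 175 were higher in Vg1.1+ cells at CD24+CD73-. At CD24+CD73+ 0 of the 175 genes were called, and their median difference in the direction seen at CD24+CD73- was 0.145. At CD24-CD73+ 83 of them were called in the same direction, where independent lists would share 10.1, and 9 in the opposite one. Of the 984 genes called at CD24-CD73+, 61.9% had the same sign at CD24+CD73+. Across all tested genes the subset differences at CD24+CD73- and CD24-CD73+ correlated at r = 0.271.

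**Figure D4:**
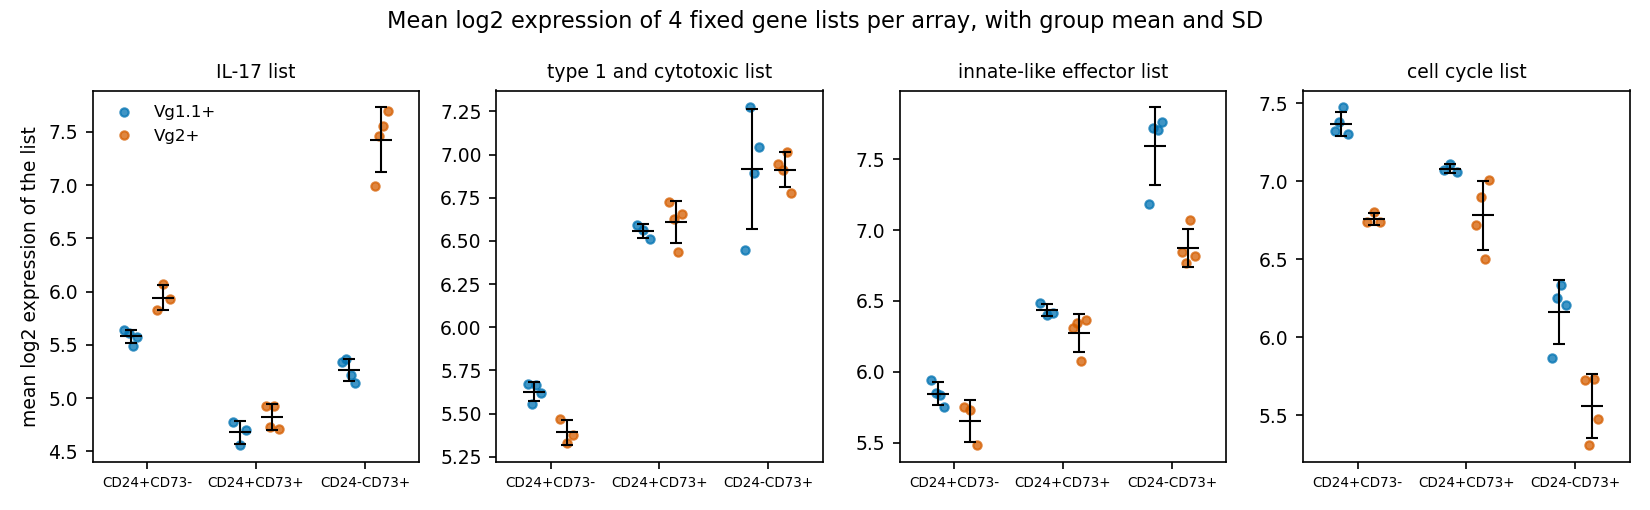
Mean log2 expression per array (points) of the measured genes of 4 fixed lists, by stage, in Vg1.1+ (blue) and Vg2+ (orange) cells, with bars for the group mean and SD. The IL-17 list reached a mean of 7.43 in Vg2+ CD24-CD73+ cells against 5.26 in Vg1.1+ cells, and the cell cycle list was lowest at that stage in both subsets.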

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

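The tests of whether 1 array widens the spread at CD24+CD73+ and of whether alpha-beta thymocytes were in 1 sample were chosen only after the result was seen, as were the fits that leave out the arrays of narrowest spread or take the spread as a covariate.

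Limma called 1 gene between the subsets at CD24+CD73+, against 175 at CD24+CD73- and 984 at CD24-CD73+, although 1579 genes had an unadjusted p under 0.05 there, against 1089 and 1880. A wrong gamma-chain label on Vg2+ CD24+CD73+ replicate 2 is argued against by a pair of probe sets for gamma-chain segments. Each lists several symbols, and both list Trgv2. The difference of the pair was 1.15 on that array, within the 0.82 to 1.86 of the other 10 Vg2+ arrays and below the 2.25 to 2.91 of the 11 Vg1.1+ arrays. A wrong stage label or a mixed sample was not tested. The array itself may account for part of the low count, since 97 genes were called without Vg2+ CD24+CD73+ replicate 2. Counts at CD24+CD73- with an array left out ran from 63 (without Vg2+ CD24+CD73- replicate 3) to 128. Whether the array acts by the spread it adds or by lying nearer to the Vg1.1+ arrays cannot be told from these counts. Vg2+ CD24+CD73+ replicate 3 had a lower median correlation with its group (0.930 against 0.947), yet 0 genes were called without it. The split that put replicate 2 with the Vg1.1+ arrays called 461. With array weights 317 genes were higher and 119 lower at CD24+CD73+. The counts were then 772 and 431 at CD24+CD73-, and 1032 and 759 at CD24-CD73+. A smaller subset difference at this stage stays open: over the 984 genes called at CD24-CD73+, the slope of the subset difference on that at CD24-CD73+ was 0.0847, which was 0.520 of the slope at CD24+CD73- (0.163) and ran from 0.429 to 0.627 of it with 1 array left out, a range on both sides of the bound set for the test.

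Markers of alpha-beta lineage thymocytes stood high on Vg1.1+ CD24+CD73- replicate 1, where 6 of the 7 measured members were the highest of their group (85.7%, against 35.8% of tested genes). Cd8a was at 7.06 against a mean of 5.19 on the other 3 arrays and Cd8b1 at 7.74 against 6.13, while Aqp11 was at 7.10 against 7.59. The wider spread of values on that array is argued against, since the 1000 genes nearest in mean level lay above the other arrays by a median of 0.062 and the list by 0.26. Alpha-beta thymocytes in the sample, which the gamma-delta gate would remove, may be the source, but the median of 0.26 lay between the bounds set for the test, and all 7 markers passed the filter in these cells, with Ptcra also in the early T precursor list. No biological explanation was tested, because the design sets nothing apart within a group.

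Cpa3 and Kit, both known from mast cells, were lower at CD24-CD73+ than at CD24+CD73+ in both subsets, with Cpa3 at -3.32 in Vg1.1+ and -3.61 in Vg2+ cells and Kit at -1.96 and -2.02 (log2 differences). Mast cells in the gate, which a gamma-delta sort would remove, could not be excluded or shown by other transcripts of mast cells. The median change of 11 other mast cell transcripts was -0.00938 in Vg2+ and 0.30 in Vg1.1+ cells, but only Slc18a2 of them passed the filter, so the test decides nothing. Among those that did not pass were the proteases Cma1 and Tpsb2, at 3.14 and 3.50 in Vg2+ CD24+CD73+ cells. From CD24+CD73- to CD24+CD73+ mean Cpa3 fell, from 8.51 to 6.87 in Vg1.1+ and from 9.38 to 7.66 in Vg2+ cells. Mean Kit rose over that step, from 5.66 to 7.70 and from 5.95 to 7.50. This argues against 1 admixture of mast cells as the sole source of both transcripts. Mast cells as a part of the signal stay open. A change within the thymocytes as CD24 is lost stays open too and was not tested.

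Other splits of the arrays of each comparison into groups of the same sizes were fitted in the same way. Chance is called excluded where fewer than 5% of splits gave as many calls, with no allowance for the number of comparisons. With 35 splits only a real split that ranks first can pass. For the gene counts of a pair of groups, 27 to 33 of the other splits called no gene, so the rank rests on few splits. In the comparison at CD24+CD73-, 1 of 35 splits (the real one) gave as many genes, 175 against at most 1 in another split. In Vg1.1+ cells the same held for the step to CD24+CD73+ (1 of 35, 668 against 150) and for that to CD24-CD73+ (1 of 35, 957 against 828). Vg2+ cells gave 1 of 35 for each step as well, with 1045 genes against 686 and 1725 against 482. For the differences between steps 2 of 100 splits each gave as many, with 8 genes against at most 50 and 432 against at most 1535. These splits mixed the subsets within each stage, which also removed the subset differences at each stage. They therefore cannot decide whether the steps differ by chance. Over the whole course 5 of 100 splits gave as many genes (340 against 765), so chance was not excluded.

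At CD24+CD73+ chance was not excluded, with 3 of 35 splits and 1 gene against 461 in the split that put Vg2+ CD24+CD73+ replicate 2 with the 3 Vg1.1+ arrays. At CD24-CD73+ the gene count did not exclude it either, with 2 of 35 splits and 984 genes against 1286. That other split set the 4 arrays of narrowest spread against the 4 of widest spread, so the gene count cannot decide on chance at this stage. With all arrays of the stage, the real split gave the largest distance between the subsets among the same 35. Splits that call several times the real count, as here with 461, 50 and 1535, may reflect a structure of the samples beside their groups, which was not tested. The counts of genes shared by both subsets were each reached by 1 of 100 splits (277 rising and 173 falling over the first step, against at most 0 and 3 in other splits, and 171 and 368 over the second, against 0 and 0). At least 98 of the 100 splits had no shared gene, as regrouped arrays seldom gave calls in both subsets, so this says nothing about sharing.

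For the number of gene lists past camera's threshold, the 5% bound was met only at CD24+CD73+ (1 of 35 splits, 6 lists against 5). The real split there also parted the arrays by spread, with SDs of 1.99 to 2.07 in Vg1.1+ and 1.71 to 1.95 in Vg2+ cells. The rank therefore cannot tell the subsets from the array spread, and chance is not called excluded. The margin was 1 list: 5 lists passed without Vg1.1+ CD24+CD73+ replicate 1 or Vg2+ CD24+CD73+ replicate 2 or 4, and none with an estimated correlation or with fry. Chance was not excluded at CD24+CD73- (19 of 35, 3 against 7) or at CD24-CD73+ (4 of 35, 6 against 7). Within Vg1.1+ cells the steps gave 17 of 35 (6 against 10) and 12 of 35 (5 against 8), and within Vg2+ cells 6 of 35 (6 against 7) and 2 of 35 (8 against 9). The differences between steps gave 9 of 100 (5 against 6) and 22 of 100 (5 against 8), so chance was excluded for none of these.

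Single arrays stood apart from the other 3 of their group in 42 of 516 tests, judged by the gap to the nearest array over the range of the group (above Dixon's critical value for 4 values). Chance alone marks about 1 in 20 groups, or 25.8 of these tests. On Vg1.1+ CD24-CD73+ replicate 1, the array of narrowest spread, the log2 values against the mean of the other 3 were Ccr6 (4.14, 3.05), Cxcr6 (7.22, 8.96), Hdac9 (4.81, 5.75), Hlf (4.46, 3.85), Id3 (6.42, 8.28), Il17rb (6.96, 7.97), Mctp1 (4.03, 4.96), Myb (7.27, 7.70), Nt5e (7.45, 8.63), Scin (3.02, 2.25), Slamf7 (5.31, 6.69), Slfn1 (7.34, 9.20), Socs2 (2.99, 4.08), Stat4 (6.62, 7.12), Top2a (7.34, 7.90) and Tuba8 (5.14, 4.36). The mean of the innate-like effector list was 7.18 there against 7.73, and that of interferon response genes 6.02 against 6.59. On Vg1.1+ CD24+CD73- replicate 1, Bub1 (6.48 against 6.84), Cd8a (7.06 against 5.19), Cd8b1 (7.74 against 6.13) and Gata3 (9.31 against 8.87) stood apart. The glycolysis list was at 6.45 against 6.18 on that array, and the alpha-beta marker list at 7.60 against 7.02.

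Fewer values stood apart on other arrays. Those of Vg1.1+ CD24+CD73- were Sox4 (7.29 against 7.17) on replicate 2, Gzma (9.85 against 9.63) on replicate 3, and Gpr183 (6.97 against 7.37), Icos (6.43 against 6.68) and Kbtbd4 (5.54 against 5.66) on replicate 4. In Vg1.1+ CD24-CD73+ cells they were Dntt (4.81 against 3.71), Gem (5.74 against 5.10) and Zdhhc2 (3.54 against 2.94) on replicate 2 and Tmem176b (5.80 against 5.98) on replicate 4. In Vg2+ CD24+CD73+ cells they were Etv5 (5.42 against 6.04) on replicate 3, where the spread of all log2 values was also narrow at 1.71 against 1.93, and Sox13 (5.30 against 5.60) and Sox4 (7.10 against 6.92) on replicate 4. In Vg2+ CD24-CD73+ cells they were Cd44 (7.01 against 7.29) and Il18r1 (9.47 against 9.92) on replicate 1, Lig4 (3.04 against 4.09) on replicate 2, and Etv5 (4.72 against 3.95) and Fcer1g (9.53 against 8.97) on replicate 3.

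The steps differed between the subsets, past limma's test of the difference itself, for the following named genes (Vg1.1+ step minus Vg2+ step, log2). From CD24+CD73- to CD24+CD73+ the difference was positive for Ccr2 (1.28), Slc35b4 (1.14) and Slc35d1 (0.99) and negative for Xcl1 (-2.02), Spa17 (-1.82), Tnfsf8 (-1.75), Aspn (-1.19) and Tgtp1 (-1.17). From CD24+CD73+ to CD24-CD73+ the difference was positive for Fabp7 (4.82), Il4 (4.12), Cd40lg (3.66), Vdr (2.83), Il17rb (2.70), Flrt2 (2.64), Il21 (2.50), Trpm6 (2.46), Inka1 (2.43), Il13 (2.19), H19 (1.93), Gem (1.86), Izumo1r (1.73), Zfp536 (1.62), Slfn1 (1.62), Myb (1.42), Hhex (1.30), Cxcr3 (1.23), Spa17 (1.22), Slc15a1 (1.17), Nusap1 (1.16) and Clec12a (0.97). It was negative for Il23r (-4.68), Ccr6 (-4.18), Abi3bp (-3.98), Il1r1 (-3.60), Tmem176a (-3.53), Tmem176b (-3.40), Pxdc1 (-3.35), Cysltr1 (-3.19), Hlf (-2.92), Zdhhc2 (-2.77), Plekhf1 (-2.55), Socs2 (-2.41), Ccr2 (-2.41), Ifngr1 (-2.15), Blk (-2.12), Il2ra (-1.92), Rasgrp1 (-1.71), Tdrkh (-1.57), Acvr2a (-1.42), Gpr183 (-1.31), Il7r (-1.12), Il18r1 (-1.03), Cd44 (-0.88), Stat4 (-0.77) and Kbtbd4 (-0.60). Of these, 3 lost their call with 1 array left out. For Slc35d1 the arrays were Vg1.1+ CD24+CD73+ replicates 1 and 2 and Vg2+ CD24+CD73- replicate 2 (adjusted p from 0.0579 to 0.0785). With arrays 1 to 3 alone the first-step calls of Slc35d1 (0.144), Aspn (0.101), Spa17 (0.0536) and Slc35b4 (0.0546) ended, and that of Aspn also with only the groups of the contrast in the fit (0.052). For Inka1 they were Vg1.1+ CD24+CD73+ replicates 1 and 3, Vg1.1+ CD24-CD73+ replicate 2 and Vg2+ CD24-CD73+ replicates 3 and 4 (adjusted p from 0.0506 to 0.0806). That call also ended without the pair of arrays of narrowest spread (0.0748), with the spread as a covariate (0.0603), with only the groups of the contrast in the fit (0.0749) and with arrays 1 to 3 alone (0.169). The call of Cxcr3 ended without any 1 of 11 arrays (adjusted p from 0.0623 to 0.121), without the filter (0.0596), with only the groups of the contrast (0.0599) and with arrays 1 to 3 alone (0.115). These arrays were Vg1.1+ CD24+CD73+ replicates 1, 2 and 3, Vg2+ CD24+CD73+ replicates 1 and 2, Vg1.1+ CD24-CD73+ replicates 2, 3 and 4 and Vg2+ CD24-CD73+ replicates 1, 3 and 4.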

How the results depend on the processing

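The fits without the pair of arrays of narrowest spread and with the array spread as a covariate were chosen only after the data had been seen. Of the 235 calls for named genes, none reversed under any alternative. All were called with the trend and robust options and with cyclic loess, and all 226 that a stricter filter still tested were called under it (9 were not given). Without a filter 222 were called, with array weights 234, with only the groups of the contrast in the fit 216, with arrays 1 to 3 alone 207, without the pair of arrays 232 and with the spread as a covariate 231. With each array left out in turn, 209 were called in every fit. On the 1000 most variable genes the distances between the subsets were 0.0223, 0.0113 and 0.132 in stage order (one-sided exact permutation p = 0.0286, 0.229 and 0.0286). The total gene counts moved by less than 1.5 times with a stricter filter, the trend and robust options or all 9450 probe sets. With the stricter filter, which tests fewer genes, the higher calls fell to 102 for the difference of the second steps (156 before) and to 72 for the whole course (128), and the lower calls of the first difference to 3 (5). Background signal was not measured here. Genes above the median of the table (4.55) on fewer than 3 arrays were not tested, and where a group mean lay under it, as the starting means of Il23r and Fabp7 did, the size of the change is less certain. Where limma called 0 genes at CD24+CD73+ under an alternative, 1579 had an unadjusted p under 0.05 with all arrays and the first choice of settings. The cause of the changes listed here was not tested, except where fewer arrays, fewer genes or a minimum fold lower a count by construction.

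Without a filter, which adds genes to the adjustment, 115 genes were called at CD24+CD73-, 0 at CD24+CD73+, and 6 lists at CD24+CD73- and 8 for the difference of the first steps passed. With only the groups of the contrast in the fit, the subset comparisons called 459, 0 and 466 genes in stage order. The steps called 1328 and 496 in Vg1.1+ cells and 673 over the first in Vg2+ cells, and the differences of steps called 14 and 236. Array weights gave 1203 (772 higher and 431 lower, against 133 and 42), 436 (317 and 119) and 1791 genes between the subsets in stage order, and 2572 and 2608 for the steps in Vg1.1+ cells. The differences of the first and second steps and of the whole course were then 445, 1048 and 919. Arrays 1 to 3 alone gave 53, 2 and 567 genes between the subsets, 1138 for the second step in Vg2+ cells, and 4 (1 higher and 3 lower), 190 and 157 for the differences. Cyclic loess gave 9 genes at CD24+CD73+ (4 higher and 5 lower, against 1 and 0) and 34 for the difference of the first steps (8 higher and 26 lower, against 3 and 5). With a minimum fold of 2 the counts between the subsets were 21, 0 and 223. The steps gave 207 and 257 in Vg1.1+ and 283 and 447 in Vg2+ cells, and the differences of the second step and of the whole course 214 and 181. Shared genes at that fold were 105 rising and 47 falling over the first step, and 50 and 97 over the second. Without the pair of arrays 367 genes were called at CD24+CD73-, 7 at CD24+CD73+ (4 higher and 3 lower) and 15 for the difference of the first steps (4 and 11), and 8 lists passed for that of the second. The calls at CD24-CD73+ were then 839 higher and 542 lower, against 495 and 489. The spread as a covariate gave 354 (228 higher and 126 lower), 0 and 1564 genes between the subsets, 1131 for the first step in Vg1.1+ cells, 41 (10 and 31) and 596 for the differences of the first step and of the whole course, 247 higher and 278 lower calls for that of the second step (156 and 276), 457 shared genes rising over the first step, and 9 lists for the second step in Vg1.1+ cells. Over the first step in Vg2+ cells, 497 higher and 548 lower, the balance turned with that covariate (786 and 651), with cyclic loess (665 and 561) and without a filter (512 and 455). Other balances near even turned as well, such as that of the second step in Vg2+ cells (878 and 847, but 948 and 1025 without the pair of arrays) and of CD24-CD73+ (266 and 301 with arrays 1 to 3 alone).

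Named calls that ended with only the groups of the contrast in the fit (adjusted p from 0.0509 to 0.292) were H1f1, Kbtbd4, Kif11, Cxcr6, Nt5e and Etv5 between the subsets, H1f5, Ccr9, Sox13, Tbx21, Id3 and Il1r1 over the second step in Vg1.1+ cells, Cd44, Egr2, Nr4a1 and Id3 in steps of Vg2+ cells, and the step differences of Aspn, Inka1 and Cxcr3. With arrays 1 to 3 alone they included Rora at CD24+CD73- (0.0623) and Sox13 at CD24-CD73+ (0.095).

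With an estimated correlation camera called 1, 0 and 1 lists between the subsets in stage order (3, 6 and 6 with the preset one). It called 3 and 2 for the steps in Vg1.1+ cells (6 and 5), 2 and 2 in Vg2+ cells (6 and 8), and 0 and 1 for the differences of the steps (5 and 5). Fry, which does not compare a list with other genes, called 0 lists at CD24+CD73+, 9 for the second step in Vg1.1+ cells and 0 for the difference of the first steps.

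Residuals of arrays sharing a replicate number in different groups had a median correlation of -0.16 (51 pairs, 6 above 0.1). For different numbers it was 0.04 (150 pairs, 65 above 0.1). A shared sort per number stays open. With the number as a block 65 genes were called at CD24+CD73-, 0 at CD24+CD73+, 250 for the difference of the second steps and 200 for the whole course, and 212 of the 235 named calls.

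With each array left out in turn, the counts between the subsets ran from 63 to 128 at CD24+CD73-, from 0 to 97 at CD24+CD73+ and from 765 to 1186 at CD24-CD73+. Those of the steps ran from 437 to 625 and from 623 to 1223 in Vg1.1+ cells, and from 701 to 1140 and from 1410 to 1804 in Vg2+ cells. The differences ran from 7 to 17, from 265 to 578 and, for the whole course, from 228 to 403. Shared genes over the first step ran from 225 to 297 rising and from 125 to 175 falling, and over the second from 123 to 203 and from 294 to 412. Without Vg1.1+ CD24+CD73+ replicate 1 the counts were 437 and 623 for the steps in Vg1.1+ cells, 265 for the second difference and 0 at CD24+CD73+, and without replicate 3 they were 623 for the second step, 276 and 0. The lowest counts of other comparisons came without Vg2+ CD24+CD73- replicate 3 (63) or 2 (701 and 228) and without Vg2+ CD24-CD73+ replicate 4 (765 and 1410). The highest at CD24+CD73+ and for the first difference came without Vg2+ CD24+CD73+ replicate 2 (97 and 17). The distances ran from 0.00917 to 0.0122, from -0.00439 to 0.0278 and from 0.0253 to 0.0383, the second reversing without Vg1.1+ CD24+CD73+ replicate 1 (-0.00439) or 3 (-0.00112). The third was 0.0253 without Vg2+ CD24-CD73+ replicate 4 (one-sided exact permutation p = 0.0571).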

Other observations

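The overlap of genes that fell in Vg1.1+ and rose in Vg2+ cells and the overlap between the first and the last stage are tests chosen only after the result was seen.

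Genes of the early T precursor list moved in both directions. From CD24+CD73- to CD24+CD73+, 2 of 18 rose and 5 fell in Vg1.1+ cells and 2 rose and 4 fell in Vg2+ cells (adjusted over the list alone, 3 higher and 5 lower, and 2 higher and 6 lower), with Dntt the largest fall in each. The list passed neither step (adjusted p = 0.302 and 0.495). From CD24+CD73+ to CD24-CD73+ 2 rose and 5 fell in Vg1.1+ cells, and 2 rose and 6 fell in Vg2+ cells (adjusted over the list alone, 2 higher and 7 lower, and 3 higher and 7 lower; adjusted p = 0.265 and 0.0501). Interferon response genes rose in 7 of 16 cases in Vg2+ cells over the latter step and fell in none, and rose in 3 over the step before it (adjusted over the list alone, 7 higher and 1 lower, and 3 higher and 0 lower). Both calls were lost with an estimated correlation (adjusted p = 0.379 and adjusted p = 0.632). Antigen processing genes with MHC class I rose in 2 of 8 cases over the latter step in Vg2+ cells, namely the peptide-loading factor Tapbp and the trimming enzyme Erap1 (adjusted over the list alone, 3 higher and 0 lower; adjusted p = 0.379 with an estimated correlation).

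Glycolysis genes rose in 2 of 8 cases as CD73 appeared in Vg1.1+ cells and in 2 as CD24 was lost in Vg2+ cells, and the list passed neither step (adjusted over the list alone, 2 higher and 0 lower, and 3 higher and 0 lower; adjusted p = 0.149 and 0.123). Type 1 and cytotoxic genes were split as CD24 was lost, with 4 of 17 higher and 3 lower in Vg1.1+ cells and 4 higher and 2 lower in Vg2+ cells (adjusted over the list alone, 4 higher and 3 lower, and 5 higher and 2 lower; adjusted p = 0.11 and 0.204). Over the step to CD24+CD73+ in Vg1.1+ cells the cell cycle list passed camera with 0 of 28 genes called (adjusted over the list alone, 0 higher and 0 lower; adjusted p = 0.361 with an estimated correlation). Myeloid and dendritic markers passed over the step to CD24-CD73+ in these cells with 1 of 8 higher, Tyrobp (adjusted over the list alone, 2 higher and 0 lower; adjusted p = 0.243 with an estimated correlation). For the difference of the latter steps, egress and homing genes had 1 of 15 higher and 4 lower and cytokine receptor and survival genes 0 of 17 higher and 4 lower (adjusted over the list alone, 1 higher and 7 lower, and 0 higher and 9 lower). Both calls were lost with an estimated correlation (adjusted p = 0.392 and adjusted p = 0.138).

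The thymic epithelium list (8 genes) passed in no comparison (lowest adjusted p = 0.109, at CD24+CD73+ between the subsets). Of markers of B cells 3 passed the filter and of erythroid cells 1, too few for a test. Of the sorted proteins and gamma-chain segments, Nt5e alone had a probe set of its own past the filter. The median, the mean and camera's direction differed in sign for these lists, none of which passed its test. Between the subsets they were the innate-like effector and cytokine receptor lists at CD24+CD73-, the early T precursor and egress lists at CD24+CD73+, and the type 1, alpha-beta, myeloid and epithelium lists at CD24-CD73+. Over the first step they were the myeloid list in Vg1.1+ and the egress and epithelium lists in Vg2+ cells, and over the second the antigen processing and alpha-beta lists in Vg1.1+ and the myeloid list in Vg2+ cells. For the differences of steps they were the innate-like effector, T-cell receptor response and, over the whole course, cell cycle lists.

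Some genes that fell as CD73 appeared rose as CD24 was lost. Of the 295 genes that fell over the first step in Vg1.1+ cells, 66 were among the 878 that rose over the second in Vg2+ cells, such as Blk, Il1r1 and Acvr2a, where independent lists would share 30.3. For the other splits of the Vg1.1+ arrays, lists of the same length were taken by the t statistic, without a threshold. These shared a median of 40.5 and at most 64, so only the real split, 1 of 35, gave as many. For a test chosen after the overlap was seen, 66 against 64 is too narrow a margin to call chance excluded. The converse overlap, of the 548 genes that fell in Vg2+ cells with the 366 that rose in Vg1.1+ cells, was 42 (23.5 from independent lists), and 8 of 35 splits of the Vg2+ arrays gave as many (up to 86, with a median of 27.5). The hypothesis of a gene set low at the middle stage in both subsets therefore stays open. The real split ranked first in 1 direction only, and narrowly.

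The other hypothesis was that the subsets differ in part before the last stage. Of the 175 genes that separated them at CD24+CD73-, 83 were called in the same direction at CD24-CD73+, where independent lists would share 10.1. Lists of the same lengths by the t statistic from the other splits of the CD24+CD73- arrays shared a median of 10 and at most 48, so 1 of 35 splits gave as many and chance was excluded.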
